A study of Mus musculus with 4 samples.

How the data were processed

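Gonads of mouse embryos at 12 days post coitum were compared on 4 arrays in 2 dye-swap pairs, with 2 arrays per comparison. Per the labels, gonads of many embryos of each genotype were pooled in several groups before total RNA was isolated. On replicate 1 of each pair the XY or Wnt4 null RNA carried Cy5, and on replicate 2 it carried Cy3. XX wild type RNA carried the other dye on every array. The labels do not say whether the arrays of a pair carried separate RNA extracts. All p-values therefore measure the spread between these arrays, which may be technical.

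The authors deposited 1 value per spot and array, a log2 ratio of the dyes, with blanks where no value was given. Base 2 was read from the first XY array, whose lowest value, shared by 6 spots, is -6.64, the log2 of a ratio of 0.01. The same base was assumed for the other arrays because their spread was alike. The normalization behind the deposited values is not given in the sources used here. The deposited columns had medians of -0.0019 and -0.0172 for XY replicates 1 and 2, and of 0.00840 and -0.0388 for Wnt4 null replicates 1 and 2, so each array had been centred near 0, by a method that stays unknown. Scale is inferred as above, and direction stays unsettled, as described next. No spot intensities were analysed here, so background correction, loess and a filter on dim spots could not be tried.

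Direction was not settled by the dyes in the labels, because no label names the numerator. The arrays of the same dye orientation, XY replicate 1 and Wnt4 null replicate 1, correlated as deposited at r = -0.62 across 12264 spots. The design text names XX wild type as the reference of both comparisons. XY replicate 1 was turned, because its deposited values were -2.22 for the Y-linked gene Eif2s3y and 1.67 for Xist, the transcript of the inactive X, against 2.25 and -1.22 on XY replicate 2. As deposited, 18 of the 19 spots past 4-fold on both XY arrays had opposite signs. The other 3 columns were left as deposited, with XX wild type as denominator; in the Wnt4 null pair 5 of 8 such spots had the same sign. The resulting direction is called likely, with that basis, and every comparison was also run with other directions. Because Eif2s3y and Xist set the turn, they are no independent check of it. Other genes also differed in sign between XY replicates 1 and 2 as deposited. Cst9 had -3.13 and 3.21, Ptgds -2.54 and 3.32, and Fst 2.48 and -3.42, while a second Eif2s3y probe had -0.64 and -0.46. For the XY pair Cst9, Ptgds and Fst argue against leaving replicate 1 as deposited. They do not settle the direction of the Wnt4 null pair.

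Gene names came from the platform annotation, updated by Entrez identifier through a RefSeq table of assembly GRCm38.p6 that was used for names only. Of 17664 spots, 14010 had 1 symbol, 13 had several and 3641 had none; 13908 matched by Entrez identifier and 0 symbols were altered. Numbering of spots in the value table and in the platform annotation matched only with rows and columns of each printed block exchanged. This was found from the values, and all gene names rest on it. In the exchanged order 10 control oligos, printed on 170 spots, took a mean of 0.467 of the variance between these spots, against 0.0928 in the deposited order and 0.139 at most in 100 random orders. On XY replicate 2 alone the share was 0.159, below the random maximum of 0.217 there. The rank correlation between 2 probes of the same gene, over 898 pairs in the XY comparison, was 0.275, against -0.00274 in the deposited order and 0.141 at most in the random orders. In the Wnt4 null comparison it was 0.0745, below the random maximum of 0.136. Among 6 orders tried, only the exchanged order with mirrored columns separated the control oligos as well (0.524), and its probe pairs correlated at -0.00829.

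Each array was centred on its median. The 12264 spots with values on all 4 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes) with a coefficient per comparison and no dye term. This fit, the gene lists, the rule for named genes and most of the other settings were fixed before the data were examined. Two-sided p-values were adjusted by Benjamini-Hochberg and called under 0.05. The fit with a probe-wise dye term shared by the 4 arrays was among those other settings. It leaves 1 residual degree of freedom per probe in place of 2, and lowers the median standard error from 0.185 to 0.0986. Means are the same with and without it, because the dye orientations are balanced. A rule of size, at least 1.5-fold in the same direction on both arrays, was counted beside the probes that passed the same limit in opposite directions. XX wild type RNA was the reference on each array and no XX wild type pool was compared with another, so its own spread is left out. The number of arrays limits the precision.

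For the gene lists, probes of a gene were averaged (10442 named probes, 9757 genes). Calls of list members are counted per gene in this way, while adjusted p-values printed beside a gene name are those of its named probe. Lists with at least 5 measured genes were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 13 lists tested, and again with an estimated correlation. The estimate lay far above 0.01 for mesonephric ducts (0.274), vessel signals (0.268), stroma and matrix (0.117) and stress and handling (0.100). It was also above for endothelium (0.0661), ovary supporting cells (0.0650), macrophages (0.0641), steroid synthesis (0.0487) and germ cells (0.0397). Calls of these lists at the preset assumed less correlation than was estimated. The estimate lay below 0.01 for early testis (-0.00856), Wnt target (-0.0346) and cell division genes (-0.0276). For these lists its size therefore does not explain a lost call. The lists covered the early testis (Sertoli lineage), steroid synthesis, supporting cells of the early ovary, vessel endothelium, vessel signals, germ cells, mesonephric ducts and tubules, red blood cells, macrophages, stroma and matrix, Wnt targets, cell division, and stress and handling. The Y-linked list, with 3 measured genes, and the X inactivation list, with 1, were too small to test. The Wnt target list shares 5 of its 16 measured genes with other lists, the ovary list 4 of 19 and the endothelial list 1 of 31; the others share 0. No table used here says which list genes the gonad itself expresses in other cells.

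The rule for named genes took, per comparison, the 10 highest and 10 lowest called genes, filled up by the smaller of the 2 ratios where fewer were called without the dye term. It also took up to 4 members per list with the largest same-sign ratios, 11 fixed genes with Wnt4 among them, and for both comparisons together the 10 highest and 10 lowest by the smallest of the 4 ratios. Where a gene had several probes, the most extreme one was named.

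The fits were tested on simulated data, 10 simulations of 12264 probes with 50 probes changed per fold size and noise drawn from the fitted prior distribution of variances. This noise was chosen after a first version, drawn from the variance of each probe, gave false calls with the dye term and no change put in; repeated, that version gives 18.2 in XY and 18.4 in Wnt4 null gonads on average (0 to 68 and 0 to 60 over 10 simulations). In the XY comparison the fit without the dye term called 0% of 2-fold, 32% of 4-fold and 69.4% of 8-fold changes, with 0.3 false calls on average. With the dye term it called 80.2%, 97.6% and 99.4%, with 9 false calls. In the Wnt4 null comparison the percentages were 0, 35.8 and 72.2 without and 74.2, 98.6 and 99.6 with the dye term, with 0.4 and 9.2 false calls. The size rule passed 13.4% of 1.5-fold and 77% of 2-fold changes in XY, with 24.3 false ones. Camera on the endothelial list found a shift of 0.2 in 10 of 10 simulations at the preset correlation and in 0 with an estimated one, and a shift of 0.8 in 10 and 9. With an estimated one a shift of 0.4 was also found in 0. The simulated genes were independent, so a call lost in that setting is by itself no sign of correlated list genes. At the preset correlation unshifted lists were called 0, 1, 2 and 0 times over 10 simulations each, for shifts of 0.1, 0.2, 0.4 and 0.8. These list simulations took their noise from the fit with the dye term and, unlike those of single probes, added no dye effect. Camera was run on them without the dye term. The simulated lists were thus cleaner than the data, and the shifts found and the false calls may not hold there.

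The common XX reference was simulated for unchanged groups, with 1 reference pool on all 4 arrays, 1 pool per dye orientation, or separate pools. Own and reference RNA were given equal shares of the noise. This share was assumed, because noise of a pool common to all 4 arrays does not enter the residuals. Alternatives covered the dye term, centring, scaling of the arrays, the variance prior, missing values, probes against genes, size limits, left-out arrays, the inter-gene correlation, the direction of the columns and gene names by deposited order. Figures were drawn with matplotlib 3.10.9.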

Results

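Total RNA from gonads of mouse embryos at 12 days post coitum, shortly after testis and ovary begin to differ, was compared on 2-colour arrays of spotted oligonucleotides. There were 4 arrays. On 2 of them XY wild type gonads were set against XX wild type gonads, and on the other 2 XX gonads lacking Wnt4, a gene for a secreted signal of the fetal ovary, were set against XX wild type gonads. Within each pair the dyes were swapped. The series title puts the question in the growth of blood vessels in the testis. Of 17664 spots, 12866 and 13967 had values on the XY arrays, and 14131 and 14533 on the Wnt4 null arrays. The 12264 spots with values on all 4 arrays were tested, and the number of arrays limits the precision. Below, errors are SD with n = 2 arrays, and positive log2 ratios mean more RNA than in XX wild type. The direction is likely but not settled: the labels do not name the numerator, and as deposited the arrays of the same dye orientation, XY replicate 1 and Wnt4 null replicate 1, correlated at r = -0.62. It rests on the design text, which names XX wild type as reference, and on Eif2s3y and Xist in the XY pair. Gene names rest on exchanging rows and columns of the printed blocks.

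XY gonads held more RNA of early testis genes and less of early ovary genes than XX gonads. Cst9, a cystatin-family gene of fetal Sertoli cells, was 9.07-fold higher (log2 3.18 ± 0.07), and Ptgds, a prostaglandin D synthase, was 7.65-fold higher (2.94 ± 0.57). Phlda2, an imprinted gene with a pleckstrin homology domain, was 9.06-fold lower (-3.18 ± 0.13), and Fst, which encodes the activin-binding protein follistatin, was 7.69-fold lower (-2.94 ± 0.65). Cst9, Ptgds, Phlda2 and Fst passed limma with the dye term (adjusted p = 0.0199, 0.0129, 0.0129 and 0.0304), not without it (0.185, 0.182, 0.165 and 0.208). Stroma and endothelial genes were also higher as lists at the preset correlation, and germ cell genes lower. With an estimated correlation 0 lists were called (camera adjusted p = 0.237, 0.197 and 0.197 for these). In simulated independent genes without a dye effect that setting also found shifts of 0.2 and 0.4 in 0 of 10 simulations each.

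Among 16 measured genes of the early testis list, 6 were called higher and 0 lower with the dye term, and 10 did not pass. Adjusted over the list alone, 9 were higher and 1 lower with it, and 6 genes passed without the dye term. Calls with the dye term can include genes whose arrays differ in sign, such as Fgf9, at -0.08 and 1.80 on the XY arrays. The list had a median log2 ratio of 0.47 and was called by camera (adjusted p = 9.77e-08; adjusted p = 0.180 with an estimated correlation). Besides Cst9 and Ptgds it held Mmd2 (2.63 ± 0.09), Tesc, a calcium-binding protein gene (2.52 ± 0.18), and Sox9, the Sertoli transcription factor gene (0.93 ± 0.08, adjusted p = 0.0361 with the dye term). Amh, the gene of the hormone that removes the Müllerian duct, averaged 0.61 ± 0.52 and did not pass (adjusted p = 0.0638 with the dye term). Of 19 measured genes of the ovary supporting cell list, 12 were called lower and 0 higher with the dye term, and 13 and 0 adjusted over the list alone, where 11 passed without the dye term. Its median was -1.001, 15 of its genes were below 0 on both arrays, and camera called it (adjusted p = 2.00e-14; adjusted p = 0.180 with an estimated correlation). Irx3, an Iroquois homeobox gene (-2.82 ± 1.07), Sp5, a transcription factor gene (-1.95 ± 0.25), Msx2, a homeobox gene (-1.80 ± 0.33), and Wnt4 itself (-1.41 ± 0.46) were among the lower ones.

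Of 42 measured stroma and matrix genes, 10 were called higher and 0 lower with the dye term, and 20 and 4 adjusted over the list alone, where 9 passed without the dye term. The median was 0.32 (camera adjusted p = 9.77e-08; adjusted p = 0.237 with an estimated correlation). Examples were Fbln2, a fibulin of the matrix (2.18 ± 0.42), Gli1, a target and effector of Hedgehog signalling (1.42 ± 0.03), Col18a1, a basement membrane collagen (1.42 ± 0.30), and Tcf21, a transcription factor gene of mesenchyme (1.25 ± 0.24). Of 31 endothelial genes, 22 were above 0 on both arrays with a median of 0.23 (camera adjusted p = 7.20e-07; adjusted p = 0.197 with an estimated correlation). Only Thbd, the gene of thrombomodulin (1.33 ± 0.20), was called higher over all genes with the dye term, and 3 genes adjusted over the list alone (1 without the dye term); Ramp2 averaged 0.75 ± 0.08 and Sox7 0.60 ± 0.04. The 38 genes of vessel signals split: with the dye term 3 were higher and 2 lower, or 9 and 4 adjusted over the list alone, where 0 passed without it. Camera did not call the list (median 0.10, adjusted p = 0.0551, and 0.0328 with the dye term). Robo1, a guidance receptor gene (1.66 ± 0.26), and Mmp2, a matrix protease gene (1.19 ± 0.10), were higher, and Adm, the gene of the vasodilator adrenomedullin (-1.64 ± 0.21), and Sema3a, a repulsive guidance signal (-1.03 ± 0.34), were lower.

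Of 21 germ cell genes, 5 were called lower and 1 higher with the dye term, 10 and 2 adjusted over the list alone (4 genes without the dye term). The list median was -0.29 (camera adjusted p = 3.36e-05, and 0.197 with an estimated correlation). The higher one was Lefty1, at -0.03 and 1.87 on the arrays. The lower ones included Stra8, a gene needed for entry into meiosis (-1.96 ± 0.31), Tfap2c (-1.35 ± 0.29), Lin28a (-1.14 ± 0.06) and Dazl (-0.78 ± 0.15). Of 11 steroid synthesis genes, 2 were called higher and 0 lower with the dye term. Adjusted over the list alone, 6 were higher and 0 lower with it, and 0 passed without it. The median was 0.49 (camera adjusted p = 0.0275, and 0.318 with an estimated correlation). Hsd17b3, an enzyme gene of testosterone synthesis, reached 1.77 ± 0.81. None of 33 cell division genes was called by limma with or without the dye term, over all genes or adjusted over the list alone (13 at an unadjusted p under 0.05 with it and 3 without), but the list as a whole was higher by a median of 0.09 (camera adjusted p = 0.00185; adjusted p = 0.197 with an estimated correlation), with Birc5 at 0.52 ± 0.19 and Cdc25c at 0.50 ± 0.14.

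Camera did not call the remaining lists in XY. The medians were -0.07 for mesonephric ducts (adjusted p = 0.0901, with Krt18 and Cldn7 of 17 genes called lower with the dye term), -0.03 for macrophages (adjusted p = 0.674, with 0 of 15 genes at an unadjusted p under 0.05 in limma with or without the dye term) and -0.15 for Wnt targets (adjusted p = 0.0979), which divided between Fst and Sp5, lower, and Ccn4, higher (0.82 ± 0.09). Red blood cell genes had a median of -0.01 and a mean of 0.03, opposite in sign, with the test downward (adjusted p = 0.937; Nfe2 0.82 ± 0.48). Stress and handling genes had a median of 0.07 (adjusted p = 0.674), with Asns, asparagine synthetase, lower (-1.21 ± 0.16). Eif2s3y, a Y-linked translation factor gene, averaged 2.24 ± 0.03 on one probe while a second probe averaged 0.09, and Kdm5d, also Y-linked, was measured on XY replicate 1 alone (1.49). Xist averaged -1.44 ± 0.33.

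**Figure D1:**
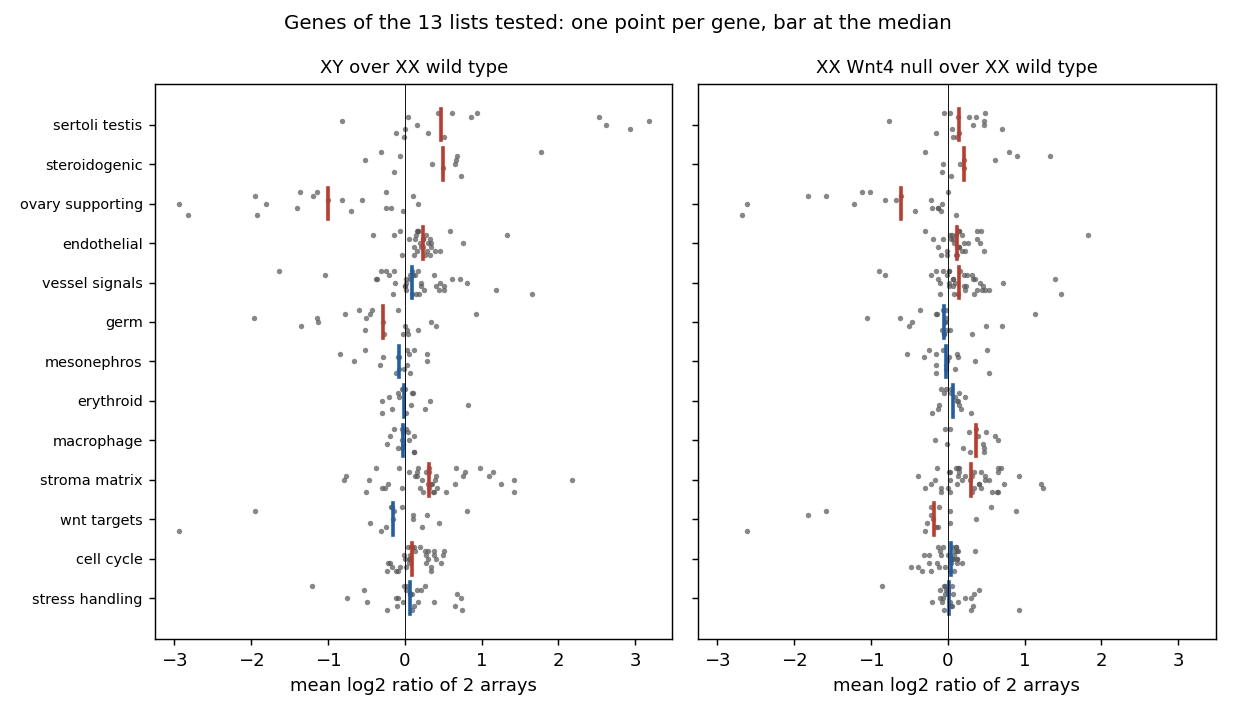
Mean log2 ratio over XX wild type of each measured gene in the 13 lists tested, 1 point per gene and averaged over 2 arrays, for XY gonads (left) and XX Wnt4 null gonads (right). The bar is the list median, red where camera called the list at the preset correlation and blue where it did not; ovary supporting genes have medians of -1.001 and -0.60.

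In XY, limma called 0 of 12264 probes without the dye term, with 686 at an unadjusted p under 0.05 where chance gives 613, and 330 probes with the dye term, 167 higher and 163 lower (2283 at an unadjusted p under 0.05). By size, 330 probes passed 1.5-fold in the same direction on both arrays, 168 higher and 162 lower, and 220 passed it in opposite directions. With centring in printed blocks 351 passed in the same direction and 102 in opposite directions. The highest also included Smoc2, a secreted matrix protein gene (3.05 ± 0.03), Ctrb1, a chymotrypsinogen gene (2.68 ± 0.39), Tmem184a (2.65 ± 0.07), Cbln1, a secreted protein of the cerebellin family (2.49 ± 0.35), and Sostdc1, a BMP and Wnt antagonist gene, which did not pass (2.24 ± 0.05, adjusted p = 0.0507 with the dye term). The lowest also included Sprr2a1 (-2.24 ± 0.02), Rhox6, an X-linked homeobox gene (-2.16 ± 0.13), Adam8 (-2.08 ± 0.02), 6430710C18Rik (-1.97 ± 0.21), Gata2, a zinc finger transcription factor gene (-1.91 ± 0.04), and Tnfrsf19 (log2 -1.81). Without XY replicate 1 the steroid and cell division lists were not called (adjusted p = 0.194 and 0.122). With the dye term 414 probes were called with deposited centring, 618 with centring in printed blocks, 1078 with arrays scaled to a common spread and 0 with each other direction of the columns tried.

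Wnt4 itself averaged -0.13 ± 0.07 in XX Wnt4 null gonads, at -0.08 on replicate 1 and -0.18 on replicate 2 (limma adjusted p = 0.781 with the dye term). Where its probe lies relative to the deleted part of the gene is not known, so this value checks nothing about the labels. XX Wnt4 null gonads held less RNA of ovary supporting cell genes than XX wild type gonads, and more of stroma, macrophage, endothelial and vessel signal genes, as lists at the preset correlation. With an estimated one 0 lists were called (0.260, 0.260, 0.271 and 0.518 for the higher ones), and without replicate 2 only the ovary list was; the replicate 1 medians were -0.000180 for endothelium and -0.0511 for vessel signals. Read as Cy3 over Cy5, which keeps the XY pair and turns Wnt4 null replicate 1 alone, the ovary list was not called (adjusted p = 0.2995), nor were macrophages or endothelium (0.408 and 0.118); stroma, vessel signals and mesonephric ducts were called higher (0.0475 each). Fst, at -2.61 ± 0.58, and Irx3, at -2.68 ± 0.02, were among the lowest. Neither passed limma singly (adjusted p = 0.0937 and 0.0711 with the dye term). In the likely directions Cbln1 was highest among named genes (2.53 ± 0.16). With Thbd (1.83 ± 0.18), Igfbp7, an insulin-like growth factor binding protein gene (1.70 ± 0.04), and Cxcl12, a chemokine gene (1.40 ± 0.03), it was called with the dye term (limma adjusted p = 0.0384 for Cbln1 and 0.0462 for the other 3). On the arrays Cbln1 had 2.41 and 2.65, and Thbd 1.70 and 1.95. With replicate 1 turned alone the arrays of these genes, and of Fst and Irx3, would differ in sign and this ranking would not hold.

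Of 19 ovary supporting genes, 2 were called lower and 0 higher with the dye term, and 11 and 0 adjusted over the list alone, where 8 passed without the dye term. The median was -0.60 and 12 genes were below 0 on both arrays (camera adjusted p = 1.80e-15; adjusted p = 0.260 with an estimated correlation). The called ones were Lgr5, a receptor gene for R-spondins (-1.82 ± 0.65), and Sp5 (-1.58 ± 0.33), both also on the Wnt target list. That list had 2 of 16 genes called lower and 0 higher, 3 and 2 adjusted over the list alone (4 genes without the dye term), and a median of -0.17 (camera adjusted p = 0.00225; adjusted p = 0.260 with an estimated correlation). Ccn4, another Wnt target, averaged 0.88 ± 0.35 and did not pass. Kitl, which encodes the ligand of the Kit receptor, averaged -1.12 ± 0.10 and did not pass.

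The stroma and matrix list had a median of 0.30, with 21 of 42 genes above 0 and 1 below on both arrays (camera adjusted p = 1.42e-09; adjusted p = 0.260 with an estimated correlation). No member was called over all genes by limma with or without the dye term, where 21 and 8 had an unadjusted p under 0.05, and 15 were higher adjusted over the list alone with it (2 genes without). Tcf21 averaged 1.21 ± 0.09, Sparc, a matrix glycoprotein gene, 0.93 ± 0.12, Col3a1, a fibrillar collagen gene, 0.66 ± 0.11, and Dcn, the gene of decorin, 0.65 ± 0.11. The macrophage list had a median of 0.37 over 15 genes (camera adjusted p = 3.20e-05, and 0.260 with an estimated correlation). Limma called 0 members over all genes, with 9 at an unadjusted p under 0.05 with the dye term and 3 without. Adjusted over the list alone, 6 were higher with the dye term, and 0 passed without it. Macrophage list examples were C1qb, a complement gene (0.65 ± 0.26), Fcer1g (0.50 ± 0.11), Pf4 (0.48 ± 0.14) and Tyrobp (0.37 ± 0.12). Vessel signals had a median of 0.15 over 38 genes (camera adjusted p = 0.000681, and 0.518 with an estimated correlation). With the dye term Cxcl12 alone was called, and 10 were higher and 2 lower adjusted over the list alone, where 1 passed without it. Robo1 averaged 1.48 ± 0.70 and Sema3a -0.82 ± 0.12. The 31 endothelial genes had a median of 0.12 (camera adjusted p = 0.000820; adjusted p = 0.271 with an estimated correlation). Thbd alone was called, also adjusted over the list alone, while Icam2 averaged 0.38 ± 0.09 and Sox7 0.43 ± 0.18.

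Early testis genes had a median of 0.14 over 16 genes (camera adjusted p = 0.0114, and 0.260 with an estimated correlation). Limma called 0 over all genes (6 at an unadjusted p under 0.05 with the dye term). Adjusted over the list alone, 2 were higher and 1 lower with the dye term, and 0 passed without it. Ptgds averaged 0.71 ± 0.19 and Fgfr2, a fibroblast growth factor receptor gene, -0.77 ± 0.03. Sox9 averaged 0.03 ± 0.34 and Amh -0.05 ± 0.39, both with arrays of opposite sign. Steroid synthesis genes had a median of 0.21 over 11 genes (camera adjusted p = 0.0114, and 0.271 with an estimated correlation). Limma called 0 of them over all genes (4 at an unadjusted p under 0.05 with the dye term). Adjusted over the list alone, 4 were higher with the dye term, and 1 passed without it. Cyp11a1, the enzyme gene that starts steroid synthesis, averaged 1.33 ± 0.13 (adjusted p = 0.0585 with the dye term) and Mc2r, the corticotropin receptor gene, 0.62 ± 0.22. Eif2s3y averaged 0.87 ± 0.92, at 1.53 on replicate 1 and 0.22 on replicate 2, and its second probe -0.31, while Kdm5d had -0.21 and 0.05. Both RNAs here are labelled XX, so the 1.53 of a Y-linked gene stays unexplained, and the same probe set the turn of XY replicate 1. Cst9, of the early testis list, was also at 1.09 on that Wnt4 null array and at -0.14 on the other. Xist had -0.48 and 0.49. Camera did not call germ cell genes (median -0.05, adjusted p = 0.420; Stra8 -1.05 ± 0.49), red blood cell genes (0.07, adjusted p = 0.683) or stress and handling genes (0.01, adjusted p = 0.420). Mesonephric duct genes had a median of -0.02 and a mean of 0.01, with the test downward (adjusted p = 0.722). Cell division genes had a median of 0.04 and a mean of -0.03, with the test downward (adjusted p = 0.655).

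In XX Wnt4 null gonads limma called 0 of 12264 probes without the dye term (354 at an unadjusted p under 0.05, below the 613 of chance) and 24 with it, 16 higher and 8 lower (1477 at an unadjusted p under 0.05). The 24 became 55 with deposited centring, 138 with scaled arrays, 150 with centring in printed blocks and 0 with other directions of the columns. Simulations without any change gave 18.4 calls (0 to 60) with noise drawn from each probe's own variance, and those with known changes 9.2 false calls with noise from the prior. By size 129 probes passed 1.5-fold on both arrays, 68 higher and 61 lower, fewer than the 706 that passed it in opposite directions. With centring in printed blocks these counts were 144 and 324. The highest also included Ctrb1 (1.68 ± 0.53), Ptn, the gene of the growth factor pleiotrophin (1.47 ± 0.28), Lpl, the lipoprotein lipase gene (1.303 ± 0.22), and Hpgd, an enzyme gene of prostaglandin breakdown (1.28 ± 0.17). The lowest also included Phlda2 (-2.42 ± 0.28), Virma (-1.88 ± 0.47), Tnfrsf19 (-1.85 ± 0.25), Gata2 (-1.48 ± 0.20) and Tkt, the transketolase gene (-1.03 ± 0.01). Of these, Lpl and Tkt did not pass with the dye term. Without Wnt4 null replicate 2 only 1 of the 8 called lists, ovary supporting cells, was called, and the adjusted p was 0.199 for stroma, 0.244 for macrophages, 0.741 for endothelium, 0.942 for vessel signals, 0.0850 for Wnt targets and early testis and 0.522 for steroid synthesis. Without replicate 1 the early testis list was not called either (adjusted p = 0.435).

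Genes of matrix, vessel and ovary lists were among those that stood on the same side of XX wild type in both comparisons. By size 77 probes passed 1.5-fold in the same direction on all 4 arrays, 34 higher and 43 lower. The highest by the smallest of 4 ratios were Cbln1, Igfbp7 (2.16 ± 0.31 in XY), Ctrb1, Thbd, Tcf21, Hic1, Gpm6b, Kcne1l, Robo1 and Sparc, and the lowest were Phlda2, Fst, Irx3, Tnfrsf19, Sp5, Gata2, Virma, Kitl, Tkt and Ncmap. Hic1, a transcriptional repressor gene, averaged 1.33 ± 0.35 in XY and 1.27 ± 0.27 in Wnt4 null gonads. Kitl averaged -1.37 ± 0.03 in XY. With the dye term 17 probes were called in the same direction in both comparisons, 11 higher and 6 lower, and 1 in opposite directions; without it the number was 0. The 17 became 42 with deposited centring, 112 with scaled arrays, 108 with centring in printed blocks and 0 with other directions of the columns.

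**Figure D2:**
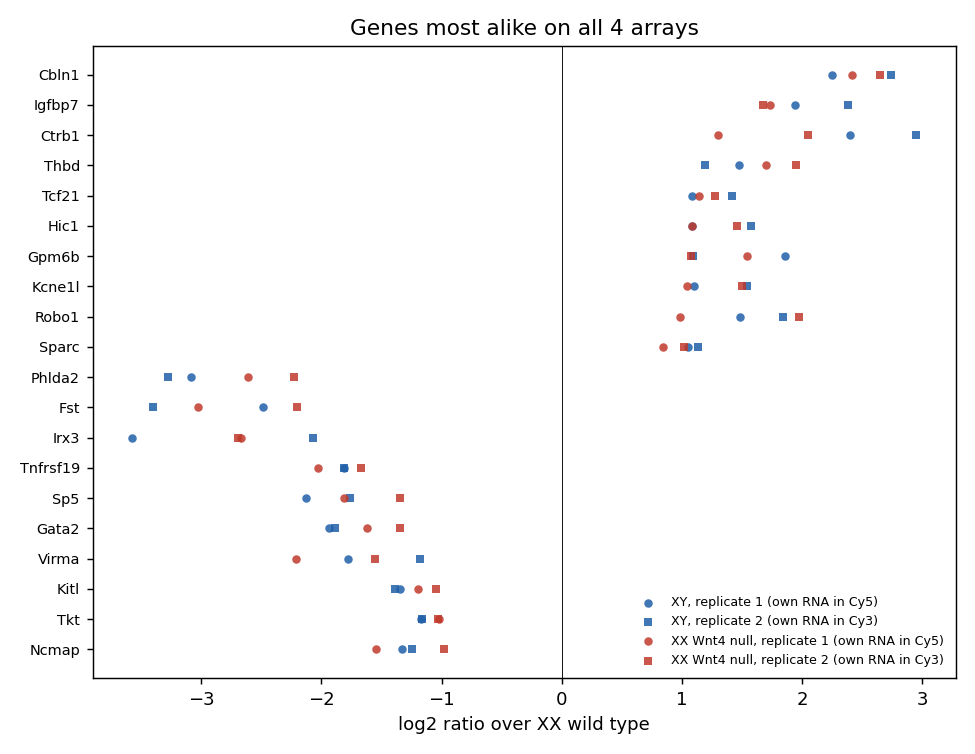
Log2 ratio over XX wild type on each array for the 10 genes highest and the 10 lowest by the smallest of their 4 ratios; circles are replicate 1 and squares replicate 2, in blue for XY and red for XX Wnt4 null gonads. All 4 values of a gene share a sign by the choice of genes; Cbln1 has means of 2.49 and 2.53.

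Independent lists would share 0.932 higher and 0.806 lower probes by size, and 0.218 and 0.106 by the dye-term calls. Unchanged groups simulated against 1 common XX reference pool shared 14.4 and 13.4 probes by size and 11.05 calls, and against 1 pool per dye orientation 2.4, 2.65 and 0.45. With noise drawn from each probe's own variance, the first version of this simulation, 1 common pool gave 3.1 and 2.35 by size and 297.05 calls, and 1 pool per dye orientation 0.35, 0.55 and 50.25. With that noise 1 common pool also gave 775 calls in XY for unchanged groups, against 330 observed and 36.55 with noise from the prior. Its shared calls therefore do not describe these arrays. Because the shares of noise were assumed, the simulations cannot decide whether the 17 shared calls exceed those of a common reference. The counterpart patterns held 3 probes that were lower in XY and higher in Wnt4 null gonads, and 0 the other way round, while 156 probes followed the dye orientation on all 4 arrays. Across probes, which are not independent replicates, the mean ratios of the comparisons correlated at r = 0.49 (rank correlation 0.36). The simulations gave 0.67 with 1 common pool and 0.50 with 1 pool per dye orientation. These values follow from the assumed equal shares of noise alone, so they are no benchmark. By rank they were 0.63 and 0.47 with noise from the prior. The covariance of the comparisons was 0.0341. Simulated covariances were 0.0260 with 1 common pool and 0.0128 with 1 pool per dye orientation (0.0142 and 0.00701 with the noise per probe). Simulated covariances and shared counts rest on the same assumed shares, which these arrays cannot estimate. Without Wnt4 null replicate 1 the correlation was 0.229, without replicate 2 it was 0.284, and without XY replicate 2 it was 0.251. The reference cannot be split further here, so the likeness of the comparisons may come in part from the shared XX RNA.

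The difference of the comparisons, tested directly, gave 0 called probes with limma without the dye term (197 at an unadjusted p under 0.05, below the 613 of chance) and 0 with it (1098). Some contrasts are therefore given as values. Cst9 averaged 0.48 in Wnt4 null gonads against 3.18 in XY (limma adjusted p = 0.253 for the difference with the dye term), and Ptgds 0.71 against 2.94 (0.209). Lgr5 averaged -1.82 against 0.11 (0.209) and Cyp11a1 1.33 against -0.06 (0.253). Some of these means join arrays of opposite sign. Cst9 had 1.09 and -0.14 on the Wnt4 null arrays. On the XY arrays Lgr5 had 0.30 and -0.08, and Cyp11a1 0.05 and -0.16. With arrays scaled to a common spread 68 probes differed. With the Wnt4 null pair turned, higher and lower exchange throughout that comparison, the correlation was -0.49 and 3 probes passed 1.5-fold on all 4 arrays.

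**Figure D3:**
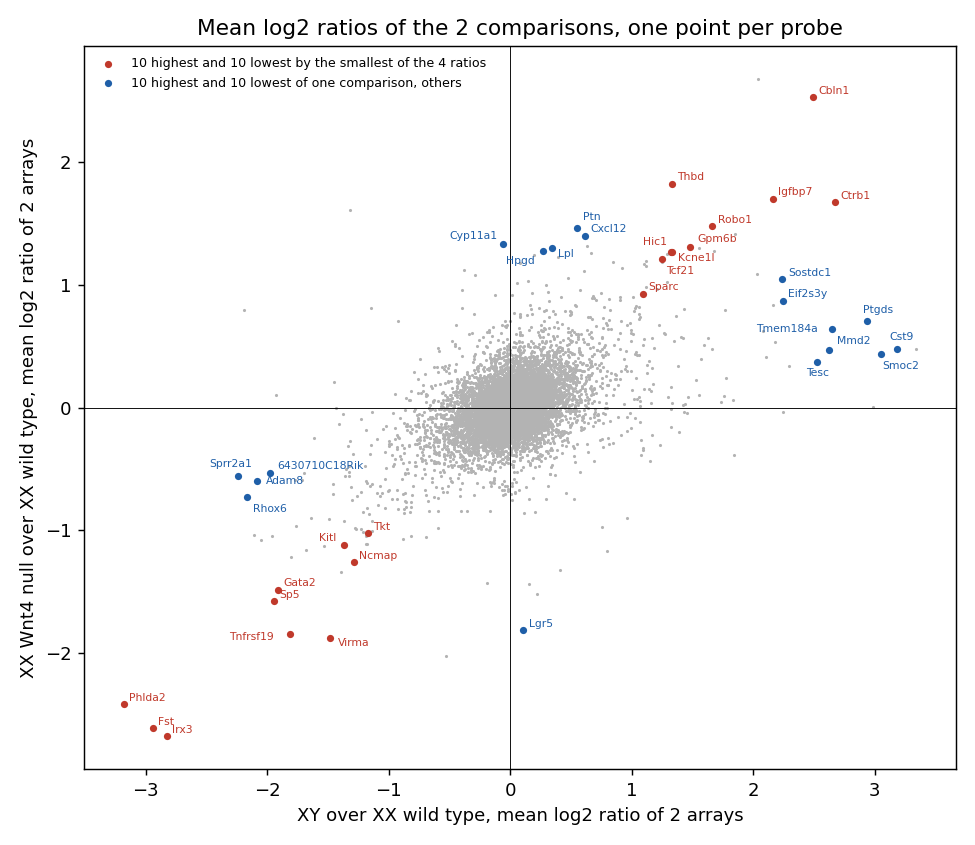
Mean log2 ratio over XX wild type in XY gonads (horizontal) and XX Wnt4 null gonads (vertical), 1 point per probe over 12264 probes, each the mean of 2 arrays. Genes in red are the 20 of the 4-array ranking and genes in blue are other genes ranked in 1 comparison; the comparisons correlate at r = 0.49, and Cst9 and Ptgds lie far to the right with small vertical values.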

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

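Choices made only after the data were seen were the directions of the columns, centring within printed blocks, gene names by deposited order, the noise of the simulations, and every combination of the dye term with another setting. Of 225 alternatives for 16 counts and correlations, 149 left the value within 1.5 times or its spread, 66 moved it and 10 reversed it. The 149 include counts of 0 that stayed 0, totals whose higher and lower parts exchanged, and a fall from 3 to 2 marker genes. They are therefore no measure of stability. For 15 called gene lists, 140 of 165 alternatives kept the call, 24 lost it and 1 reversed its direction. Unlike the 225, these leave out the other directions of the columns and gene names by deposited order. Signs as deposited called 0 XY lists, and names by deposited order 0 in either comparison. Read as Cy5 over Cy3, 7 XY lists were called, 2 higher and 5 lower in place of 5 and 2. With the Wnt4 null pair turned, 8 were called there, 2 higher and 6 lower in place of 6 and 2. For 147 results of named probes, each counted per comparison, 1247 of 1323 kept their side of the threshold, 71 passed it, 65 of these with the dye term, and 5 turned sign. The other directions and names by deposited order are left out of this count too. Where no cause is named, it was not tested. Spot brightness was not analysed here, so limits from signal over background are unknown, and the fit with the dye term and an array left out has no residual degrees of freedom and was not run.

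With the dye term, 330 probes were called in XY, 24 in Wnt4 null gonads and 17 in both; limma on the 2 XY arrays alone called 3. With deposited centring, 55 probes were called in Wnt4 null gonads and 42 in both with the dye term. With arrays scaled to a common spread these counts were 1078, 138 and 112, and 68 for the difference. With centring in printed blocks they were 618, 150 and 108, and 7 for the difference. A limit of 1.3-fold gave 682, 306 and 172 probes in XY, in Wnt4 null and on all 4 arrays, and 2-fold gave 118, 28 and 20, as a looser or stricter limit must. An estimated correlation left 0 and 0 called lists, as did gene names by deposited order. Probes with at least 1 value per comparison correlated at 0.324.

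Leaving out 1 array at a time, calls without the dye term ranged from 0 to 3 in XY, probes by size from 330 to 1488 in XY, 129 to 1961 in Wnt4 null and 82 to 139 on all 4 arrays, since fewer arrays must pass. Called lists ranged from 1 to 8 in Wnt4 null gonads, correlations from 0.229 to 0.466 and rank correlations from 0.139 to 0.377. Without Wnt4 null replicate 2 the vessel signal list reversed (adjusted p = 0.942, and 6.98e-05 without replicate 1). In Wnt4 null gonads Xist ranged from -0.485 to 0.485 and Amh from -0.329 to 0.229 over the arrays, and Sox9 from -0.213 to 0.270. Xist was at -0.0149 with deposited centring and -0.0299 with scaled arrays.

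Arrays of opposite dyes correlated at -0.309 and -0.237 (rank -0.391 and -0.342). With signs as deposited, the dye term gave 0, 0 and 0 calls, 0 probes passed on all 4 arrays, 0 lists were called in XY, correlations were 0.138 and 0.164 by rank, and 1 of 3 marker genes (Eif2s3y, Xist, Wnt4) had its predicted sign on both arrays. These counts check nothing independently, because Eif2s3y and Xist set the turn and Wnt4 does not test the labels. Read as Cy5 over Cy3, or as Cy3 over Cy5, the dye term gave 0, 0 and 0 calls, 706 Wnt4 null probes passed by size, 5 on all 4 arrays, 3 lists were called in Wnt4 null (3 higher and 0 lower as Cy3 over Cy5, the ovary list not among them), and correlations were -0.0168 and -0.0179 by rank. The markers with their sign were 0 of 3 as Cy5 over Cy3, and 2 of 3 as Cy3 over Cy5, which leaves the XY pair as reported and turns Wnt4 null replicate 1 alone. With the Wnt4 null pair turned, dye-term calls were 0, 0 and 0, 3 probes passed on all 4 arrays, correlations were -0.488 and -0.358, and 2 of 3 markers had their sign.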

Other observations

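The dye term, left-out arrays, the estimated correlation of lists and the correlations of single opposite-dye arrays were fixed beforehand; the tests of explanations in this part, and the orders of spots, were chosen only after the results were seen. Outside the rule for named genes, and picked after their values were seen, 4 more named genes were called with the dye term in XX Wnt4 null gonads. They were Heyl, a Notch target gene (mean log2 1.26, and 0.67 in XY), Plod2, a collagen lysyl hydroxylase gene (1.28 and 1.68), Hesx1, a homeobox gene (1.25 and 1.295), and Nupr1, a stress response gene (1.32 and 0.64). Another 5 called probes have no symbol, and 1 of them, lower in XY (-1.32) and higher in Wnt4 null gonads (1.61), was called in opposite directions. Rspo1, the gene of a secreted activator of Wnt signalling, averaged -1.93 in XY, called with the dye term, and 0.11 in Wnt4 null gonads, at -0.65 and 0.86 on the arrays.

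Probes measured on both arrays of only 1 comparison were not in the fits. In XY, 9 of 252 such probes passed 1.5-fold higher and 4 lower on both arrays, with 24 in opposite directions, among them Gjb2, a connexin gene, at 1.54 and 2.39. In Wnt4 null gonads 8 of 1474 passed higher and 13 lower, with 381 in opposite directions, among them Pappa at -2.27 and -0.96 and Ets1, an endothelial and lymphoid transcription factor gene, at 0.73 and 0.69. Of the fixed genes, Bmp2 had -0.55 and 0.69 on the XY arrays and 0.03 on Wnt4 null replicate 1, Sry and Uty had a value on 1 Wnt4 null array each, and Ddx3y had no probe.

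Of the 6 orders of spots tried, gene lists were called only with rows and columns of each printed block exchanged (7 in XY and 8 in Wnt4 null gonads, against 0 and 0 in each other order). The hypothesis is that value table and platform annotation number spots of a block in different orders. In the exchanged order probes of the same gene had a rank correlation of 0.275 in XY, above the highest of 100 random orders, 0.141; in Wnt4 null gonads it was 0.0745, below the random maximum of 0.136. For a chance match, 0 of 100 random orders separated control oligos as well over the mean of 4 arrays. On XY replicate 2 alone 1 did (0.217 against 0.159). This argues against a random order within blocks only, because random orders are no measure of the structured orders tried. The exchanged order with mirrored columns separated them better (0.524 against 0.467), so the control oligos do not single out the exchanged order. The probe pairs of the mirrored order correlated at -0.00829 in XY. No biological explanation was tested.

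Read in the likely directions, arrays of the same dye orientation correlated across the comparisons at 0.62 and 0.68, and arrays within each comparison at 0.06 and -0.46. As deposited the first value is -0.62, and with the Wnt4 null pair turned both values of the same dyes are negative. Change of the same genes in both comparisons as the whole cause is argued against in the likely directions. There arrays of opposite dyes had a mean correlation of -0.273, against 0.649 for arrays of the same dyes. With Wnt4 null replicate 1 turned alone this contrast is lost. Opposite-dye arrays then correlate at -0.31 and 0.24, and same-dye arrays at -0.62 and 0.68. In either reading each Wnt4 null array correlated with the XY arrays in opposite signs, which such a cause alone would not give. These signs rest on the turn of XY replicate 1. Dye bias of single probes stays open, although in the likely directions most values go with it. Opposite-dye arrays correlated at -0.237 or lower across the comparisons and within the Wnt4 null pair. In the Wnt4 null pair 706 probes passed 1.5-fold in opposite directions against 129 in the same one. Centred within printed blocks, 324 passed in opposite directions and 144 in the same one. Part of the 706 thus went with whole blocks and not with single probes. The XY pair, also of opposite dyes, correlated at 0.06, but a difference between the sexes there cannot be separated from a dye bias. The XY pair can thus not decide the question. Genes alike on all 4 arrays cannot come from a bias that follows the dye alone, and a common XX reference stays open for these. By size 34 higher and 43 lower probes were observed, against 14.4 and 13.4 simulated with 1 common pool (3.1 and 2.35 with the noise per probe). The simulated counts rest on an assumed share of noise, so this excess does not decide it.

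Stroma and macrophage lists were higher in XX Wnt4 null gonads at the preset correlation (medians 0.30 and 0.37), but not called with an estimated one (adjusted p = 0.260 for both) or without replicate 2. Mesonephros carried over with its ducts stays open. The duct list had a median of -0.0174, below the stroma list by more than the SD of its genes, 0.277, but this mean hides -0.24 on replicate 1 and 0.35 on replicate 2. On replicate 2, on which the lists rest, the gap to the stroma list was 0.186 (SD 0.487). The labels say that mesonephroi were removed. A lower share of supporting cells, which would raise every other type alike, stays open too. The macrophage list exceeded the red blood cell list by 0.299 (SD 0.250) on the mean, but by 0.246 (SD 0.289) and 0.459 (SD 0.491) on the single arrays. These SDs are of single genes and not of a median, so this rule could hardly argue against a lower share. Germ cell, duct and red blood cell lists were not called (medians -0.05, -0.02 and 0.07), but the endothelial list was at the preset correlation (0.12). A biological effect of losing Wnt4 was not tested apart from these explanations and stays open.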
